A study of Homo sapiens with 19 samples.

How the data were processed

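RNA from 5 human tissues was measured on 19 custom 2-colour arrays for alternative splicing. Per the labels, total RNA was extracted from frozen tissue and amplified, and tissue and pool were labelled with Cy5 and Cy3 using random primers, with the dyes swapped on the second array of each slide. The comparator pool mixed equal parts of 9 amplified RNAs, namely the 5 tissues and 4 glioblastomas. As the labels read, 1 RNA source stood behind each tissue, so the replicates are slides. The array scanner, background correction and normalization method are not given in the sources used here.

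The values used are the deposited log10 ratios of tissue to pool, a single value per probe and array, which were multiplied to the log2 scale for every value printed. The base of the logarithm is not stated. It was inferred from the values: where a transcript was found in a single tissue, the ratios in the other tissues are fixed by the share of that tissue in the pool. Over 126 such probes of liver and muscle the root mean square error of this model was 0.0501 with base 10, 0.0755 with base e and 0.0923 with base 2, and the best base was 6.6. Over 45 probes of bone marrow and testes the errors were 0.0646, 0.0846 and 0.0891, and the best base was 30, the end of the range tried, so the 2 sets of probes point to different bases. If the base is another, every log2 size changes by the same factor. No direction and no test without a size limit would then change, but counts at 2-fold or at 0.5 and the estimated parts of the pool would.

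The direction, tissue over pool with the dye-swapped arrays already turned, was inferred from the labels and from liver and muscle genes being positive in their tissue in both positions. Arrays of different tissues in the same position had a median r of 0.29 (lowest −0.06), and those in opposite positions −0.28 (lowest −0.59). The centring stays unknown in its method: the arrays of each tissue shared a mean over all probes, with differences of at most 9.2e-10 on the log10 scale, and these means ran from −0.00863 in bone marrow to 0.00651 in muscle. The array medians on the log10 scale were 0.0162, −0.0071, 0.0126 and −0.0065 in bone marrow, 0.0054, −0.012, 0.0111 and −0.0087 in brain, 0.0098, 0.0172 and −0.0031 in liver, 0.0085, −0.01, 0.0281 and −0.0092 in muscle, and −0.0106, 0.0097, 0.0101 and −0.008 in testes, each in order of slide and position except liver, which lacks position 2 of its first slide, and testes, whose first array is in position 2. No value was missing.

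Array position had an effect on 5093 of 6541 probes (median size 0.12, 99th percentile 1.11 on the log2 scale). Position 1 and 2 arrays of a slide were therefore averaged to 1 replicate, 2 per tissue. Liver replicate 65 was a single array. Testes arrays from slides 63 and 73 were averaged to 1 replicate, because both lacked a partner, although a muscle array carries the same code as the testes array of slide 73.

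Gene names came from the platform's annotation: 4908 probes had 1 gene, 422 had several and 1211 had none, and no gene was named from the latter. All 241 gene identifiers matched the RefSeq gene table of assembly GRCh38.p14, which changed 0 symbols. Its coordinates were not used. A gene's value was the mean over its probes (2 to 75), which understates a change confined to some of them.

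Each tissue was compared with the mean of the other 4 in limma 3.58.1 under R 4.3.3 (lmFit, contrasts, eBayes), with all 5 tissues in the model, 5 residual degrees of freedom and a prior of 2.68 for probes. Benjamini-Hochberg adjustment at 0.05 was applied over 6541 probes or 241 genes per tissue. A moderated F test covered all tissues. Probe patterns were tested with limma's diffSplice in 238 genes with at least 3 probes. Lists were tested with camera at a preset correlation of 0.01, and with an estimated correlation and fry beside it. Figures were drawn with matplotlib 3.10.9.

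Of 19 gene lists fixed before the data were examined, 2 had at least 5 measured genes, namely splicing regulators and genes with known alternative exons. The measured genes of the others were SYP (neuron), MOBP (glia), TPM1 (skeletal muscle), ALDOA and LDHA (glycolysis), APOC2, FGG and ITIH4 (plasma protein), ASS1 and EPHX2 (liver metabolism), DMTN and UROD (erythroid), AURKB and MCM7 (cell cycle), TBPL1 (spermatogenesis), TIMP1 (stromal), PSMA4 and PSMC3 (proteasome), and RPL38 and RPS6 (ribosomal protein). The myeloid, lymphoid, testis somatic, adipose and immediate early lists had 0.

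The rule for named genes was also fixed in advance. Per tissue it took the 10 largest rises and 5 largest falls among genes past the threshold whose 2 replicates lay on one side of the 8 replicates of the other tissues, then up to 4 more genes of a list that passed or was named for the tissue with its members that did not pass, and for probe patterns the 6 genes of smallest p with their most deviating probe. Genes with probes in opposite directions, PSMA4, RPS6, TIMP1 outside liver, and the brain and testes values of further splicing regulators were chosen after their values were seen.

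Alternatives listed in advance took each array as a replicate with position and slide as terms, or split the mixed testes pair. Slide series (slides 62 to 66 and 73 to 77) was taken as a block with that pair split too, because its slide codes span both series. Others were each position alone, median centring, quantile normalization, and a filter on unvarying probes and on missing values. The rest were stricter thresholds, tissue against pool, the median over probes, other probe-pattern tests, other list tests and leaving out each replicate. The corrections of the liver array and of the testes replicate for array position, and the count of opposite probes, were added after seeing the data. Slide pairs behind these corrections numbered 8 and 6.

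The tests were tried on simulated replicates drawn from the spread of the real probes, with values independent of each other. For brain, with 6541 probes and 50 changed at each size, 32% were recovered at 0.1, 86% at 0.25, 92% at 0.5 and 100% at 1 on the log2 scale, with 15 false calls. The F test over 5 tissues recovered 4%, 68%, 84% and 98% at these sizes, with 13 false calls. For testes, of 20 genes among 241 changed at each size, 75% were recovered at 0.05 and 100% at 0.1 and 0.2, with 3 false calls. For muscle, of 20 genes among 238 with a single changed probe at each size, 75% were recovered at 0.25 and 100% at 0.5 and 1, with 15 false calls among the genes left unchanged, a rate above the nominal 5% that bears on the counts of probe patterns. The list test in testes called 1 of 20 unchanged lists and 20 of 20 at a shift of 0.05 or 0.1. Its genes were drawn without correlation, whereas the estimated correlation of the real splicing regulators was 0.086. It therefore does not give the rate of false calls for that list.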

Results

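The series compared the messenger RNA of 5 normal human tissues, brain, muscle, liver, bone marrow and testes, on custom 2-colour arrays made to read alternative splicing. Each of 19 arrays hybridised amplified RNA of a tissue together with a common pool, and each value is the ratio of tissue to pool at a probe. The pool held 9 RNAs in equal parts, namely the 5 tissues and 4 glioblastomas, which are tumours of glial origin. Brain, muscle, bone marrow and testes had 4 arrays each and liver had 3. A slide carried an array with the dyes one way (position 1) and an array with the dyes swapped (position 2), so the arrays of a slide were averaged and each tissue had 2 replicates, 10 in all. Liver replicate 65 was a single position 1 array. A testes array in position 1 bore a code that a muscle array also carried, and it was averaged with the testes array left without a partner as replicate 63-73. All 6541 probes had a value on every array, 4908 of them with a single gene name from 241 genes, and a gene had a median of 17 probes. No depth applies to array ratios, and the small number of arrays limits the precision.

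Arrays of the same tissue and position had a median Pearson r of 0.93 across probes (0.85 to 0.96 over 9 pairs), and probes are not independent replicates. Arrays of the same tissue in opposite positions had a median r of 0.38 over 18 pairs, and the 4 such pairs of brain lay between −0.04 and 0.05. After averaging the positions, r between the 2 replicates was 0.871 in brain, 0.931 in muscle, 0.90 in liver, 0.928 in bone marrow and 0.975 in testes. The median probe SD between replicates ran from 0.01 in testes to 0.04 in muscle on the log2 scale. Every p-value below comes from limma. Those of single probes and genes measure this spread between slides, which may be technical, because the labels name no separate donors within a tissue. Those of diffSplice pool the spread over the probes of a gene, although probes read on the same arrays are not independent. Those of camera compare a list with the other genes.

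The first question was which transcripts differed among the tissues at all. FGG, the gamma chain of fibrinogen, and APOC2, a cofactor of lipoprotein lipase, stood above the pool in liver and below it in the other 4 tissues. TPM1, a tropomyosin of the thin filament, and ALDOA, a glycolytic aldolase, stood above the pool in muscle alone among the 5 tissue means. NRM, a protein of the inner nuclear membrane, and MLF1 did so in testes, and PFN2, an actin-binding profilin, was highest in brain. By limma's moderated F test 3987 of 6541 probes (61.0%) differed among the 5 tissues after Benjamini-Hochberg adjustment, as did 213 of 241 genes. Most differences were small: the median range over the 5 tissue means was 0.16 on the log2 scale, 400 probes spanned 2-fold or more, and 112 spanned 4-fold or more. With slide series as a block, 2526 probes differed. That setting also splits testes replicate 63-73, because its slide codes span both series, and with that split alone 2387 probes differed. The split leaves these testes arrays, of opposite positions, unaveraged, so the position effect adds to the spread shared by all tissues.

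**Figure D1:**
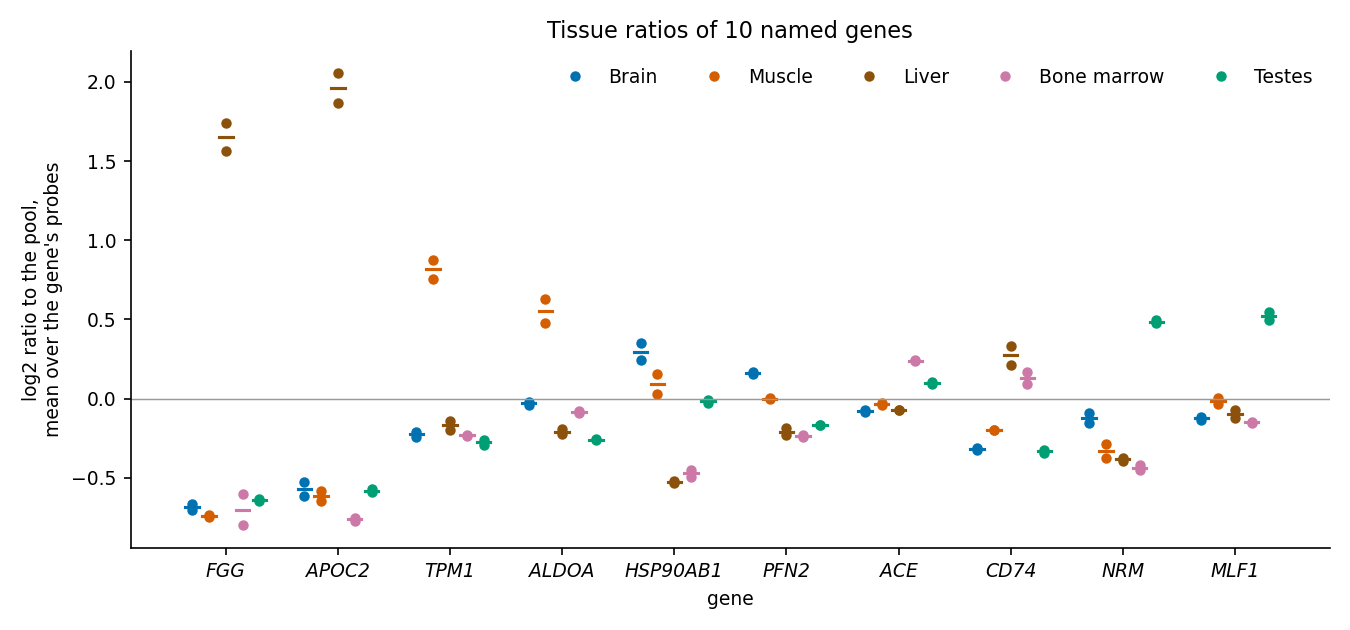
Mean log2 ratio to the pool over the probes of each of 10 named genes (vertical axis), with a point per replicate (2 per tissue) and a bar at the tissue mean. FGG and APOC2 reached 1.65 and 1.96 in liver, and TPM1 0.82 in muscle.

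Brain was set against the mean of the other 4 tissues. In each such contrast a large rise in a single tissue raises that mean for the other tissues and can appear in them as a fall. HSP90AB1, a cytosolic chaperone, rose most, by 0.53 on the log2 scale (SE 0.03, 1.44-fold, adjusted p = 9.3e-06), and all 15 of its probes were higher. PFN2 rose by 0.31 (SE 0.01, 21 of 28 probes higher, adjusted p = 4.3e-07), and so did PRNP, the prion protein, by 0.31 (SE 0.01, adjusted p = 1.7e-07). SYP, a membrane protein of synaptic vesicles and the measured member of the neuronal list, rose by 0.17 (SE 0.01, adjusted p = 1.4e-05) with 14 of its 32 probes higher. MOBP, a protein of myelin and the measured member of the glial list, was higher by 0.07 (SE 0.01, adjusted p = 0.0017).

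Other rises in brain were DMTN (0.24), an actin-bundling protein, UBE2V2 (0.22), a ubiquitin-conjugating enzyme variant, TRAPPC3 (0.20), which tethers vesicles, YWHAB (0.19), a 14-3-3 protein, and SNRPB (0.17), a core protein of spliceosomal particles. WARS1, the cytosolic tryptophanyl-tRNA synthetase, rose by 0.30 as a mean over 75 probes, of which 13 were higher and 8 lower. With the median over probes WARS1 stood at −0.04 and its call was lost, as were the calls of TRAPPC3 and MOBP. Among genes whose 2 brain replicates lay on one side of all replicates of the other tissues, the largest falls were SNRPF (−0.16), another spliceosomal core protein, ACE (−0.14), the angiotensin-converting enzyme, DDX39A (−0.13), an RNA helicase of mRNA export, CD151 (−0.08), a tetraspanin, and BAG6 (−0.07), a chaperone. The fall of CD151 did not pass the test when either brain replicate was left out, and neither it nor BAG6 passed in position 1 arrays alone. TIMP1, a metalloproteinase inhibitor of connective tissue and the measured member of the stromal list, fell in brain by 0.40 (SE 0.03, adjusted p = 1.4e-05).

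In all, 36 genes were higher and 37 lower in brain, and 168 did not pass, so 49.3% of the called genes were higher. After centring each array on its median this share was 68.4%, and with the median over the probes of a gene it was 28.2% (22 higher, 56 lower). Of the probes 696 were higher, 32 of them by 2-fold or more, and 721 were lower, 9 by 2-fold or more. With slide series as a block 453 probes were higher and 309 lower, and without brain replicate 64 the counts were 312 and 159, with 17 lower genes, and without 75 they were 425 and 216.

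Because the arrays were built for splicing, the next question was whether the probes of a gene moved apart from each other. In WARS1 probe 16207 was 2.69 higher in brain than in the other tissues (SE 0.14), while the median probe of the gene lay at −0.04. A single probe of DHRS4, a dehydrogenase, number 9343, was 2.28 higher (SE 0.13), and the gene as a whole was 0.08 higher. SRSF5, an SR splicing factor, had probe 21827 at 1.90 and a gene mean of 0.12. ARPP19, a phosphatase regulator, had probe 12756 at 1.62 and a gene mean of 0.07. Probe 270 of PFN2 was 0.98 higher, and probe 21022 of SLC25A14, a mitochondrial carrier, was 0.82 higher. limma's diffSplice test called a probe pattern in brain against the other tissues in 193 of 238 genes with at least 3 probes, and 7 of these had a probe that departed 2-fold or more from the rest of its gene. Without brain replicate 64 the count of patterns was 126. The largest gene-level adjusted p among the 6 named genes was 3.7e-50, that of SLC25A14. Values this small, here and in the tissues below, rest on treating the probes of a gene as independent. No probe sequence or exon position was used here, so a departing probe is not tied to a given exon or junction.

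**Figure D2:**
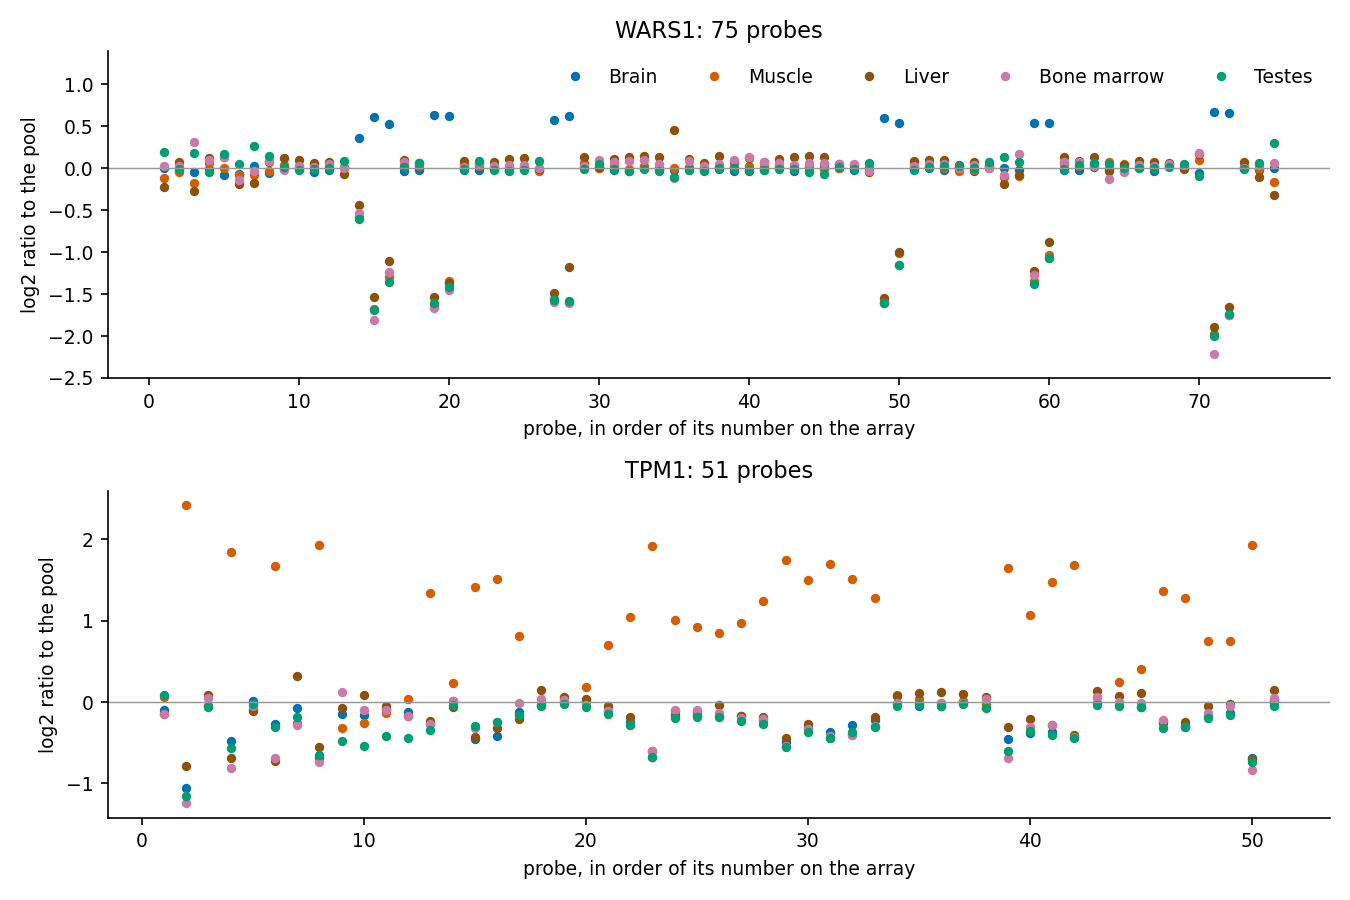
Mean log2 ratio to the pool (vertical axis) of each of the 75 probes of WARS1 (top) and the 51 probes of TPM1 (bottom) in order of probe number (horizontal axis), with a point per tissue. In brain 13 WARS1 probes were called higher while most lay near 0, and in muscle 35 TPM1 probes were called higher.

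Muscle was compared in the same way. TPM1 rose by 1.04 (SE 0.03, 2.06-fold, adjusted p = 2.3e-08), with 35 of 51 probes higher. The muscle array of slide 73 in position 1 read TPM1 at 0.61 over the pool, against 0.87 to 0.90 on the other 3. ALDOA rose by 0.70 (SE 0.03, adjusted p = 5.0e-07), and LDHA, the other measured glycolysis gene, by 0.08 (SE 0.02, adjusted p = 0.0024). Genes of mitochondrial energy supply were among the largest rises, namely ATP5F1B, the catalytic beta subunit of ATP synthase, by 0.41 (24 of 28 probes higher), COX7B, a cytochrome c oxidase subunit, by 0.38, and SLC25A3, the phosphate carrier, by 0.24. They were named by size, and no list of such genes was tested.

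FEZ2 rose by 0.52 in muscle, RPL38, a protein of the large ribosomal subunit, by 0.42, and KRT7, a keratin of simple epithelia, by 0.31. PKIA, an inhibitor of protein kinase A, rose by 0.26. MPDU1, which serves mannose transfer in the endoplasmic reticulum, had a mean of 0.22 that came from 3 higher probes of 21, and with the median over probes it stood at −0.01. RPL38 differed widely between muscle replicates (SD 0.18, n = 2). Among genes whose muscle replicates lay apart from all others in that way, the largest falls were ASS1 (−0.15), argininosuccinate synthase, NFKBIB (−0.15), an inhibitor of NF-kappa-B, SRSF9 (−0.15) and SRSF7 (−0.14), both SR splicing factors, and YWHAB (−0.12). The fall of NFKBIB did not pass the test when either muscle replicate was left out. TIMP1 fell in muscle by 0.46.

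In muscle 60 genes were higher and 55 lower, and 126 did not pass, a share of 52.2% higher that was 30.7% after quantile normalization. Of the probes 854 were higher, 124 of them by 2-fold or more, and 703 were lower, 12 by 2-fold or more. With slide series as a block 25 genes and 394 probes were lower, and without muscle replicate 62 the counts were 33 and 384.

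Probe patterns in muscle were led by TPM1, whose probe 2635 was 3.48 higher (SE 0.15) against a gene mean of 1.04. In ALDOA probe 3612 was 2.26 higher. In TMEM208, a protein of the endoplasmic reticulum, probe 16768 was 2.43 higher (SE 0.08), the only higher probe among 23, while 8 were lower. SLC2A5, the fructose transporter, likewise had a single higher probe of 30, number 19066, at 2.33. COCH, an extracellular matrix protein, had probe 4005 at 2.08, and NIT1, an amidase, had probe 22416 at 1.03 and a gene mean of 0.004. The test called 205 of 238 genes, 30 of them with a probe that departed 2-fold or more, and the largest adjusted p of the 6 named genes was 3.3e-73.

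Liver had the largest single gene and probe rises of the 5 tissues, although muscle had more probes that rose by 2-fold or more (124 against 42). APOC2 rose by 2.59 (SE 0.04, 6.03-fold, adjusted p = 2.8e-10) with a ratio to the pool of 1.96 (SD 0.13, n = 2), and all 13 probes were higher. FGG rose by 2.34 (SE 0.05, 5.08-fold, adjusted p = 1.7e-09), and ITIH4, a plasma inhibitor heavy chain, by 1.01 (SE 0.03, 2.02-fold, adjusted p = 3.3e-08). All 3 measured genes of the plasma protein list thus rose. Of the liver metabolism list, ASS1 was 0.06 higher (SE 0.03, adjusted p = 0.0740) and EPHX2, a soluble epoxide hydrolase, 0.01 higher (SE 0.01, adjusted p = 0.695), and neither passed, though both did with the median over probes (0.08 and 0.06).

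TIMP1 rose by 0.83 in liver, with all 8 probes higher, and CD74, the invariant chain of MHC class II, by 0.45, with 7 of 17 probes higher. Smaller rises were those of FAM156A (0.15), IRF3 (0.13), a transcription factor of the interferon response, MED8 (0.11), a Mediator subunit, CDK7 (0.10), a kinase of transcription and the cell cycle, and ACAA1 (0.10), a peroxisomal thiolase. The call of MED8 was lost in position 2 arrays alone, with testes replicate 63-73 split, and against the pool, where it stood at 0.02. The largest falls among genes whose liver replicates lay apart from all others were HSP90AB1 (−0.50), HNRNPA1 (−0.48), an RNA-binding protein of splicing measured by 2 probes, RPL38 (−0.39), AURKB (−0.38), a mitotic kinase, and LSM4 (−0.28), a protein of the U6 particle. Over the pool, the HSP90AB1 replicates read −0.52 and −0.53 in liver, and nearly as low in bone marrow, at −0.49 and −0.45. They read 0.35 and 0.24 in brain, 0.15 and 0.03 in muscle, and −0.01 and −0.03 in testes.

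In liver 44 genes were higher and 107 lower, and 90 did not pass, so 29.1% of called genes were higher, against 17.1% after median centring and 41.0% after quantile normalization. With the median over probes the majority turned, with 77 genes higher and 54 lower (58.8% higher). Of the probes 1575 were higher, 42 of them by 2-fold or more, and 1606 were lower, 26 by 2-fold or more. Liver replicate 65 lacked a dye-swapped array, so its dye effect did not average out. Correcting that array by the position difference of the other tissues, an alternative chosen after seeing the data, left 463 probes and 27 genes higher, and 1270 probes and 106 genes lower. All 15 named rises and falls of liver passed after that correction, the falls of HNRNPA1 and RPL38 at −0.31 and −0.30, and ASS1 then passed at 0.09 (adjusted p = 0.0080). With slide series as a block 585 probes were higher and 1048 lower, with 22 genes higher, and without replicate 65 there were 722 higher probes.

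Among the probes of liver, number 8792 of FGG was 6.36 higher than in the other tissues (SE 0.17, 82.2-fold), and another FGG probe, 13242, was lower by −0.55. IRF3 had probe 8100 at 3.77 (SE 0.11) against a gene mean of 0.13, and LTAP1 had probe 8877 at 2.81 (SE 0.06) against 0.08. Probe 22416 of NIT1 was lower in liver, by −0.74, as was probe 19187 of MFF, a mitochondrial fission factor, by −0.77. PFDN5, a prefoldin subunit, had probe 21413 at −1.06. The test called 234 of 238 genes, 18 with a departure of 2-fold or more, and the largest adjusted p of the 6 was 4.4e-65.

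In bone marrow ACE rose most among the genes whose replicates lay apart from all others, by 0.26 (SE 0.01, adjusted p = 6.4e-07), as a mean over 18 probes of which 6 were higher and 3 lower. With the median over probes ACE stood at 0.03 and did not pass. PTBP1, a repressor of alternative exons, rose by 0.23 (SE 0.02, adjusted p = 8.2e-06), with 7 of 8 probes higher. SELENBP1, a selenium-binding protein, rose by 0.23 with 10 of 13 probes higher, and ST6GALNAC4, a sialyltransferase, by 0.15 with 14 of 15 probes higher. APOC2 fell most, by 0.81 (SE 0.04, adjusted p = 3.1e-06), with all 13 probes lower. Most of this size came from liver, which lies in the mean of the other tissues. Over the pool, the APOC2 replicates read −0.75 and −0.77 in bone marrow, and 1.87 and 2.05 in liver. They read −0.53 and −0.62 in brain, −0.65 and −0.58 in muscle, and −0.57 and −0.59 in testes.

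Further rises in bone marrow were SLC25A1 (0.24), the mitochondrial citrate carrier, CCNDBP1 (0.23), a cyclin D binding protein, NFKBIB (0.19), ASS1 (0.16), SSR4 (0.11), a subunit at the protein translocon, and MYL6 (0.11), a myosin light chain. The call of SSR4 was lost with testes replicate 63-73 split, with or without slide series as a block, and without bone marrow replicate 77. It was also lost after median centring (limma adjusted p = 0.0528), with the median over probes (0.04, adjusted p = 0.0806) and at an adjusted p of 0.01. HNRNPDL, an RNA-binding protein, fell by 0.35, NRM by 0.35, ITIH4 by 0.28 and KRT7 by 0.26. Of the erythroid list, UROD, a heme synthesis enzyme, rose by 0.08 (SE 0.01, adjusted p = 0.0017) and DMTN was 0.03 higher (adjusted p = 0.101), short of the threshold but past it with the median over probes. Of the cell cycle list, MCM7, a replicative helicase subunit, rose by 0.10 (SE 0.02, adjusted p = 0.0055), a call lost without replicate 77, and AURKB stood at 0.08 (SE 0.04, adjusted p = 0.173), also past it with the median. TIMP1 fell by 0.28. The myeloid and lymphoid lists had no measured gene.

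In bone marrow 43 genes were higher and 83 lower, and 115 did not pass, a share of 34.1% higher that was 51.6% after quantile normalization and 56.2% with the median over probes, so that the majority turned in both. Of the probes 689 were higher, 22 of them by 2-fold or more, and 1229 were lower, 42 by 2-fold or more. With slide series as a block 23 genes were higher and 54 lower, with 383 higher probes, and without replicate 77 the gene counts were 21 and 52 and the probe counts 374 and 696.

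The probe patterns of bone marrow included VEGFA, the vascular growth factor, whose probe 12000 was 2.01 higher (SE 0.14) against a gene mean of 0.04. Probe 3354 of SLC25A14 was 1.14 higher, and probe 4312 of ELOVL1, a fatty acid elongase, 1.03 higher. Probe 19187 of MFF was 0.85 higher although the gene mean was −0.12 and 27 of its 55 probes were lower. Probe 8100 of IRF3 was lower by −1.81 and probe 22416 of NIT1 by −0.70. The test called 223 of 238 genes, 27 with a departure of 2-fold or more, and the largest adjusted p of the 6 was 2.0e-70.

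In testes NRM rose by 0.80 (SE 0.02, 1.75-fold, adjusted p = 2.1e-08), with 19 of 25 probes higher, and MLF1 by 0.62 (SE 0.02, 1.53-fold, adjusted p = 2.1e-08). RAN, the GTPase of nuclear transport, rose by 0.36 with 10 of 12 probes higher, and DDX39A by 0.34. TBPL1, a relative of the TATA-binding protein needed for sperm maturation and the measured member of the spermatogenesis list, rose by 0.22 (SE 0.01, adjusted p = 3.1e-06). AURKB rose by 0.24 (SE 0.04, adjusted p = 0.0014). TPM1 and ALDOA each fell by 0.32, with 37 of 51 and 18 of 28 probes lower. Both rose in muscle, which lies in the mean set against testes and adds to these falls. Over the pool, the TPM1 replicates read −0.26 and −0.29 in testes. They read −0.21 and −0.24 in brain, −0.14 and −0.20 in liver, and −0.23 and −0.24 in bone marrow.

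Other rises in testes were HNRNPA1 (0.39), MMAB (0.31), a cobalamin enzyme, MFF (0.29, 36 of 55 probes higher), HNRNPH3 (0.29) and HNRNPDL (0.28), both RNA-binding proteins. Against the pool HNRNPDL was at 0.03 and did not pass. The 2 probes of HNRNPA1 read −0.22 on both testes arrays in position 1 and 0.50 and 0.42 on those in position 2. The sign against the pool thus differed with the dye orientation, while the rise over the other tissues passed in position 1 arrays alone and in position 2 arrays alone. CD74 fell by 0.31, MED8 by 0.20 and SLC25A3 by 0.17, and TIMP1 rose by 0.31.

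In testes 99 genes were higher and 44 lower, and 98 did not pass, a share of 69.2% higher that was 53.7% after quantile normalization. With the median over probes the majority turned, with 51 genes higher and 73 lower (41.1% higher). Of the probes 1301 were higher, 54 of them by 2-fold or more, and 1181 were lower, 10 by 2-fold or more. With the liver array corrected 751 testes probes were lower, since liver is among the tissues set against testes, and without replicate 63-73 or 74 the lower probes were 239 or 237, the higher probes 754 or 761 and the lower genes 26 or 29.

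Among the probe patterns of testes, MFF had probe 14629 at 1.12 (SE 0.05) against a gene mean of 0.29, and NRM had probe 10789 at 2.19 (SE 0.06) against 0.80. NIT1, whose probe 22416 stood out in muscle, liver and bone marrow, had another probe, 1477, at 1.20 (SE 0.05). Probe 15789 of ASNS, asparagine synthetase, was 1.05 higher, probe 4985 of ELOVL1 0.90 higher and probe 22727 of PRPF3, a spliceosomal protein, 1.07 higher. The test called 216 of 238 genes, 20 with a departure of 2-fold or more, and the largest adjusted p of the 6 was 4.7e-75.

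Splicing regulators were compared as a group, since 22 genes of the list fixed in advance were measured. In testes 16 of the 22 rose, 1 fell and 5 did not pass, and the list lay 0.09 above the other genes (camera adjusted p = 0.0054; adjusted p = 0.195 with an estimated correlation). Against the pool the testes shift of the list was 0.035 and did not pass (adjusted p = 0.195). CLK3, a kinase of SR proteins, rose by 0.23, HNRNPU and SRSF9 by 0.17 each and HNRNPC by 0.19, and SRSF8 fell by 0.05. The 2 probes of HNRNPC read −0.32 and −0.26 on the testes arrays in position 1 and 0.32 and 0.25 on those in position 2, and against the pool the gene stood at −0.003 and did not pass. Its testes call was lost in position 1 arrays alone and with the liver array corrected (adjusted p = 0.0517). In muscle 2 rose, 11 fell and 9 did not pass, and the list lay below the other genes by −0.07 (camera adjusted p = 0.0041; adjusted p = 0.181 with an estimated correlation). HNRNPC fell by 0.28, PTBP1 by 0.18 and HNRNPK by 0.11, while U2AF2, which marks the 3 prime splice site, rose by 0.17. Over the pool HNRNPC read −0.62 and −0.84 on the muscle arrays in position 1, and −0.05 and −0.02 on those in position 2. Its muscle fall passed in each position alone. The calls of HNRNPC in both tissues were lost with testes replicate 63-73 split, with or without slide series as a block, and that of U2AF2 with the median over probes.

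The same list had 6 rises and 2 falls in brain (camera adjusted p = 0.112), 3 rises and 13 falls in liver (adjusted p = 0.421) and 4 rises and 9 falls in bone marrow (adjusted p = 0.561). In brain HNRNPC rose by 0.26 and SNRPB by 0.17, and PTBP1 fell by 0.16. In bone marrow the mean of the list was −0.01 while its median was 0.01 and the camera direction was up. Adjusted over the list alone, the counts of rises and falls were the same in all 5 tissues.

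**Figure D3:**
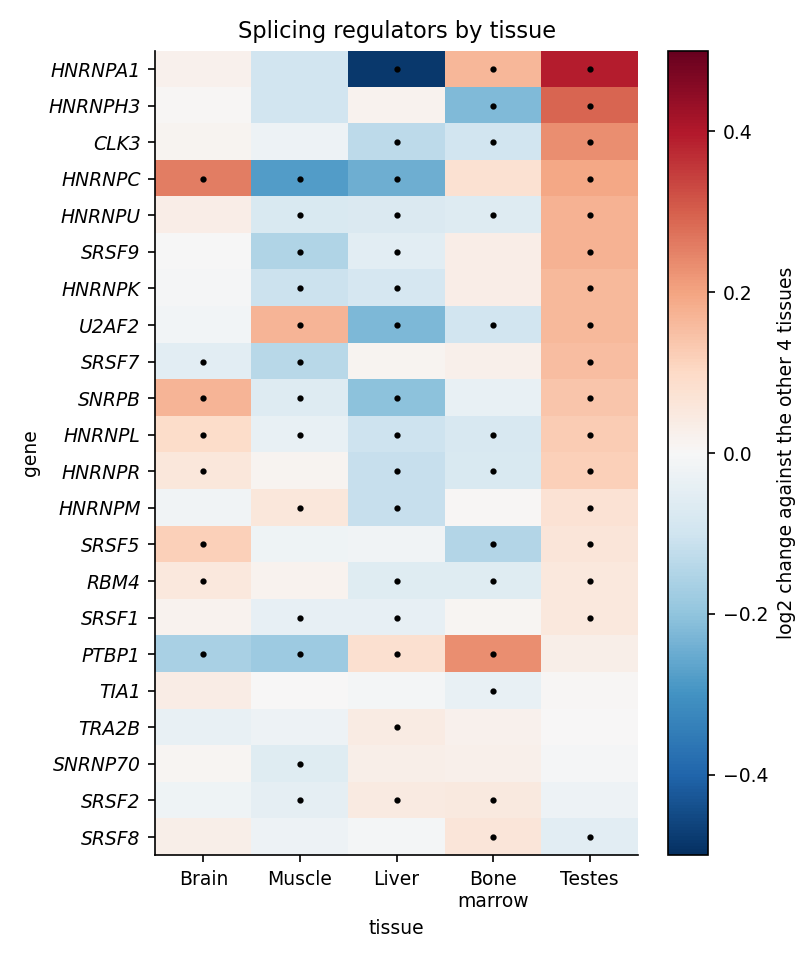
Log2 change of each of the 22 splicing regulators (vertical axis) in a tissue against the other 4 tissues (horizontal axis), with a dot where the limma adjusted p was under 0.05. The testes column holds 16 rises and 1 fall, and the muscle column 2 rises and 11 falls.

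The other list large enough to test held 6 genes with well known alternative exons, CLTA, MACROH2A1, MYL6, PTBP1, SLC25A3 and TPM1. Its gene-level shift did not pass the camera test in any tissue (adjusted p = 0.233 in brain, 0.999 in muscle, 0.911 in liver, 0.561 in bone marrow and 0.388 in testes). Rises and falls numbered 0 and 2 in brain, 2 and 2 in muscle, 1 and 3 in liver, 3 and 2 in bone marrow and 2 and 2 in testes. Adjusted over the list alone, brain had 1 rise and 2 falls and the other counts were the same. In muscle the mean of this list was 0.16, carried by TPM1, while its median was −0.02 and the camera direction was down, and in testes the mean was −0.05 and the median 0.02.

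A probe pattern is most direct where probes of a gene moved in opposite ways in the same tissue. With both probes past the threshold and at least 0.5 away from 0, a size chosen after seeing the data, there were 31 such cases in 25 genes, 0 in brain, 4 in muscle, 11 in liver, 11 in bone marrow and 5 in testes. A fall among them may reflect a rise of the same probe in another tissue, and such cases were not separated. The lower FGG probe in testes, 8792 at −1.65, was 6.36 higher in liver. Probe 21958 of ASS1 was higher by 2.57 in bone marrow (SE 0.12) and lower in liver (−1.05) and testes (−0.67). Bone marrow lies in the mean set against liver and testes, so its rise lowers both of these values. Probe 22367 of the same gene was higher by 1.36 in testes (SE 0.10) and lower in bone marrow (−0.60), and probe 22230 was higher by 0.90 in liver (SE 0.04). At gene level ASS1 rose by 0.16 in bone marrow and stood at 0.06 in liver, which did not pass.

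Other cases were DPM2, a regulator of mannose transfer, in liver (probes 1297 and 23085 at 1.13 and −1.20), and SLC2A8, a glucose transporter, in bone marrow (probes 1060 and 741 at 2.26 and −0.85). VEGFA in bone marrow had probe 20458 at −0.91 beside probe 12000 at 2.01. In muscle CLDND1, a claudin-like membrane protein, had probes 809 and 23766 at 1.55 and −0.64, and CD74 had probes 12904 and 5631 at 1.12 and −1.25. All of these probes passed limma's test, with adjusted p of at most 0.0042. After the correction of the liver array 27 cases were found, 25 of them among the 31.

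**Figure D4:**
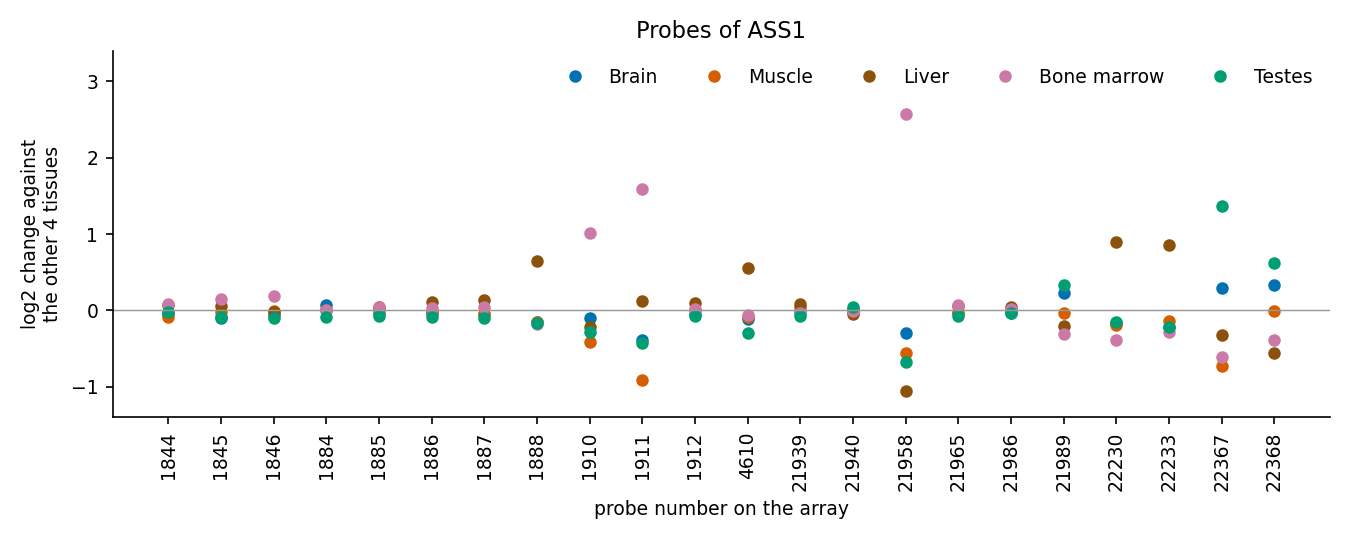
Log2 change against the other 4 tissues (vertical axis) of each of the 22 probes of ASS1 by probe number (horizontal axis), with a point per tissue. Probe 21958 was at 2.57 in bone marrow and −1.05 in liver, and probe 22367 at 1.36 in testes and −0.60 in bone marrow.

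The 1633 probes without a single gene name held large changes too. In muscle 46 of them rose by 2-fold or more, led by probes 14225 and 14224 at 3.77 and 3.72 (SE 0.09 each), and in brain 8 did, led by probes 21484 and 21637 at 2.60 and 2.43. In liver and in bone marrow 10 each fell by 2-fold or more.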

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

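The test for single arrays far from the rest was set before the data were examined. It covered 75 pairs of a named gene and a tissue with 4 arrays. Chance passes about 1 in 20 where the 4 values share a single normal spread. Here the arrays of a tissue lie in 2 positions, so that rate need not hold. Where values part by position, a single array can hardly pass. 2 gene values passed, both on the muscle array of slide 73 in position 1. On that array TPM1 had a log2 ratio to the pool of 0.61, against 0.87 to 0.90 on the other 3 muscle arrays. LDHA had 0.055 there, against 0.11 to 0.12 on the others. Genes that did not pass went both ways: ALDOA (0.31) and RPL38 (−0.19) were lowest there, while FEZ2 (0.48) and COX7B (0.36) lay between the others. Across all probes that array had r of 0.29 and 0.32 with the muscle arrays in position 2. The muscle array of slide 62 in position 1 had 0.62 and 0.67 with them. The departure of that array may thus be wider than the genes that passed. Liver, with 3 arrays, was not tested.

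The pairing of replicates into tissues was tested as planned. Over 100 pairings of the 10 replicates, the real one gave 3987 probes that differed and was the only 1 with so many, while the highest other gave 1558. The replicates of a tissue read as slides of the same RNA. Their median r was 0.93, against −0.01 between tissues, so the real pairing was bound to rank high. The test shows that slides of a tissue agree, and it cannot tell tissue differences from donor differences.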

How the results depend on the processing

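The corrections of liver array 65 and of the testes replicate were chosen only after the results were seen, and the other alternatives before. The 92 values of named genes were recomputed under 23 of them, leaving aside the 2-fold threshold: of 2116 values, 2065 kept their direction and side of the threshold, 31 lost the call, 17 gained it and 3 turned. The turned values were HNRNPC in testes against the pool (−0.0030) and, with the median over probes, WARS1 in brain (−0.035) and MPDU1 in muscle (−0.0085). The median gives less weight to single probes, and the cause of the other changes was not tested except where fewer arrays or a stricter threshold is the setting. Other calls lost were CD151, BAG6, TRAPPC3 and MOBP in brain, HNRNPC, NFKBIB and U2AF2 in muscle, MED8 in liver, SSR4, MCM7 and ACE in bone marrow, and HNRNPDL and HNRNPC in testes. Calls gained were ASS1 and EPHX2 in liver, and DMTN and AURKB in bone marrow. The filter on missing values removed nothing, and leaving out the least varying probes changed no call of a named gene and moved no count by over 1.5 times. With that filter the share of called genes that were higher moved from 29.1% to 23.9% in liver and from 69.2% to 73.5% in testes. The testes correction moved no count by over 1.5 times.

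Requiring 2-fold left probes higher and lower of 32 and 9 in brain, 124 and 12 in muscle, 42 and 26 in liver, 22 and 42 in bone marrow and 54 and 10 in testes. Genes were then 0 and 0 in brain, bone marrow and testes, 1 and 0 in muscle (TPM1) and 3 and 0 in liver (APOC2, FGG, ITIH4), against 117, 144 and 155 at an unadjusted limma p under 0.05 in the tissues with none. Probe patterns numbered 7, 30, 18, 27 and 20 in the same order, and 397 probes differed among the tissues. At an adjusted p of 0.01 probes higher were 407 in brain, 530 in liver and 338 in bone marrow, and lower 239 in brain, 358 in muscle, 1068 in liver, 750 in bone marrow and 352 in testes. Genes higher were 24 in liver and 24 in bone marrow, genes lower 36 in muscle and 55 in bone marrow, and 2409 probes differed among the tissues.

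With position 1 arrays alone, probes higher and lower were 335 and 150 in brain, 567 and 441 in muscle, 227 and 791 in liver, 227 and 575 in bone marrow and 732 and 215 in testes. Genes higher were then 22 in liver and 19 in bone marrow, genes lower 21 in brain, 46 in bone marrow and 26 in testes, and 1823 probes differed among the tissues. With position 2 arrays alone liver had 318 and 922 probes.

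With the mixed testes pair split, probes higher were 437 in brain, 423 in liver and 367 in bone marrow, and lower 292, 381, 999 and 616 in brain, muscle, liver and testes. Genes higher were 20 in liver and 21 in bone marrow, genes lower 24 in brain, 26 in muscle and 51 in bone marrow, and 2387 probes differed among the tissues. With slide series as a block, which also splits that pair, probes higher were 453 in brain, 585 in liver and 383 in bone marrow, and lower 309, 394 and 1048 in brain, muscle and liver. Genes higher were 22 in liver and 23 in bone marrow, genes lower 25 in muscle and 54 in bone marrow, and 2526 probes differed among the tissues. By the codes each series had 1 slide per tissue, except testes with slides 73 and 74 in the later series. Slide 73 also carries muscle arrays in both positions. The testes code may thus be wrong, and that array in the wrong series of the block. In both settings the testes pair, of opposite positions, was not averaged, so the position effect entered the spread shared by all tissues. No test within a series was run.

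Against the pool, 1168 bone marrow probes were higher, 410 and 319 brain probes higher and lower, 515 testes probes lower, and the splicing regulators in testes shifted by 0.035 (adjusted p = 0.195). Quantile normalization gave 941 higher probes in liver, 65 higher genes in bone marrow, and 62 and 95 lower genes in brain and muscle. Median centring gave 28 higher genes in liver and 24 lower in brain. No scaling moved the median of all probes or genes by over 0.1. Each array as a replicate gave 805 higher probes in liver and 56 lower genes in brain. With the median over probes, genes higher and lower were 22 and 56 in brain, 32 and 30 in muscle, 77 and 54 in liver and 51 and 73 in testes, and 35 were lower in bone marrow, so the majority of called genes turned to higher in liver and bone marrow and to lower in testes. The liver correction gave 463 higher probes and 27 higher genes in liver and 751 lower probes in testes.

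With an estimated correlation the shifts of splicing regulators, −0.075 in muscle and 0.086 in testes, no longer passed (adjusted p = 0.181 and 0.195). fry, which does not compare a list with other genes, called the known alternative exon genes in brain (−0.068), muscle (0.16), liver (−0.051), bone marrow (0.0064) and testes (−0.050), and splicing regulators in brain (0.028) and liver (−0.079), besides muscle (−0.055) and testes (0.11), where camera had called them too, with adjusted p from 3.8e-05 to 0.0113.

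Leaving out each replicate, with a lone replicate assumed to vary like the other groups, gave these ranges. In brain higher probes ran from 312 to 867, lower probes from 159 to 1201, lower genes from 17 to 61 and probe patterns from 126 to 206. Replicate 64 gave the lowest of each, and brain replicate 75 (425 and 216 probes), muscle replicate 62 and both testes replicates (392 and 381 lower probes) moved brain counts too. In muscle lower probes ran from 384 to 824 and lower genes from 33 to 60, the lowest without replicate 62. In liver higher probes ran from 722 (without replicate 65) to 2011 and higher genes from 24 (without 76) to 51, and without replicate 76 or testes replicate 63-73 higher probes were 1015 or 1029. In bone marrow higher and lower probes ran from 374 to 826 and 696 to 1335, and genes from 21 to 49 and 52 to 95, lowest without replicate 77, and without replicate 66 probes were 400 and 775. In testes higher and lower probes ran from 754 to 1400 and 237 to 1746, and lower genes from 26 to 52. Without replicate 63-73 they were 754, 239 and 26, without replicate 74 they were 761, 237 and 29, and without brain replicate 75 lower probes were 729. The number of arrays limits all of these counts.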

Other observations

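The tests of the small liver rises, of the pool makeup and range in brain, and of the liver cases of opposite probes were chosen only after the results were seen. The tests of the large liver rises and of all cases of opposite probes used the liver correction, which was added after seeing the data. The test of shuffled gene names used the count of opposite probes, also added after seeing the data. None of these tests was thus fixed before the data were examined.

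Housekeeping complexes had few genes on the array. RPS6, a protein of the small ribosomal subunit, rose in muscle by 0.10 (SE 0.02, limma adjusted p = 0.0011) and fell in brain by 0.10 (adjusted p = 0.0018) and in liver by 0.09 (adjusted p = 0.0015), and RPL38 rose in muscle by 0.42 and fell in liver by 0.39. PSMA4, a core proteasome subunit, rose in brain by 0.15 (SE 0.02, adjusted p = 4.2e-04) and fell in bone marrow by 0.17 (adjusted p = 2.0e-04). PSMC3, a subunit of the proteasome cap, stood at 0.02 in brain (adjusted p = 0.222) and 0.01 in bone marrow (adjusted p = 0.534), and passed in neither.

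If the missing dye swap of liver replicate 65 gave the first pattern, the 1533 small liver rises of under 2-fold, they should be lost when that array is corrected by the position difference of the other tissues, and 376 kept their call. Their median size was 0.10 (quartiles 0.08 and 0.13, median SE 0.026) before the correction and 0.07 (quartiles 0.05 and 0.09, median SE 0.029) after it, so calls ended through smaller sizes and a larger SE. Of the 1575 higher probes of any size, settings that balance array position left 227 (position 1 alone), 318 (position 2 alone) and 805 (position as a term), the first 2 with fewer arrays. Slide series as a block, which balances no position, left 585. Splitting testes replicate 63-73 alone, which leaves the liver arrays as they were, left 423. The last 2 settings leave that testes pair, of opposite positions, unaveraged. The position effect then widens the spread shared by all tissues, so calls can end whatever the liver imbalance is. The imbalance may account for part of the small rises, though lost calls alone do not show it. Across all probes the slope of the liver change on the position difference was 0.249 (r = 0.22), close to the 0.25 that the imbalance alone gives. The imbalance was thus seen in the liver changes at about its predicted size, but this slope does not single out the small rises. All 42 rises of 2-fold or more stayed. The correction moves a liver change by 0.25 of the position difference, and the 99th percentile of the position effect over all arrays was 1.11. At most probes the correction is thus too small to make or remove a 2-fold rise, so these kept calls decide nothing. Array centring and a difference between tissues stay open for the small rises: 1191 kept their call after median centring, which shifted the median liver change by only 0.022, and of 3270 quiet probes, at a median ratio of 0.063 to the pool in liver, 968 were called higher before the position correction and 73 after it, at a median of 0.037.

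The second pattern is that probes high in brain rose little over the pool. At 26 probes at least 1 above every other tissue, many of them of WARS1 and the rest of ARPP19, DHRS4, PSMA4, SRSF5 or without a gene name, brain lay at 0.63 over the pool and the other tissues at −1.24. Under the pool model with base 10 this would need 4.78 of 9 parts of the pool to hold the transcript (quartiles 3.77 and 5.01; 4.65 as a median over the 5 genes), against 0.97 in muscle, 0.76 in liver, 0.81 in bone marrow and 1.93 in testes (quartiles 1.29 and 2.26), where a transcript of a single tissue should give 1. The model thus also misses in testes, and in liver, where the upper quartile was 0.90. With base 10 the highest liver ratio to the pool was 12.1-fold, above the 9-fold that 9 equal parts allow. The liver and muscle probes also served to choose the base with 1 part assumed, so their values near 1 are no independent baseline. For the larger value in brain a candidate explanation is that the 4 glioblastoma RNAs, whose arrays were not analysed here, hold these transcripts too. A narrower range of the brain arrays could not be told apart from this, since brain fell 0.743 times as far below the pool as other tissues at liver and muscle probes, between the limits set for either answer.

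The third pattern is genes with probes in opposite directions, 31 cases. A lower probe there can reflect a rise of that probe in another tissue, which these counts do not separate. The liver imbalance is argued against as the source of all of them, since 25 stayed after the correction, but 20 of the 31 lay outside liver, where 18 stayed and the imbalance weighs little. In liver 7 of 11 stayed, and for the 4 lost (HNRNPH3, SLC25A3, TPM1 and WARS1) it stays open. Probes that read another gene stay open, because 100 shuffles of the gene names gave a median of 133 cases (115 to 149), more than the 31 found but not excluding a minority of such probes. Different transcripts of a gene in different tissues may be a source, as a hypothesis that these values do not test.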
